A study of Homo sapiens with 3 samples.

How the data were processed

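ARID1B ChIP-seq was made in HEK293FRT cells in 2 replicates, with 1 input sample. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated, and libraries were amplified by PCR and size-selected. Per the submitters' processing notes, bcl2fastq 2.20.0.422, Bowtie2 2.3.4.1 and MACS2 2.1.2 were used and the genome build was hg38. The settings, the peak threshold, the treatment of duplicate reads and whether the input served as control are not given in the sources used here, and the antibody is not given there either. The authors deposited 1 peak list per ChIP replicate, so peaks of the replicates can be compared as separate calls. Each deposited list gives a chromosome, a start, an end and a whole-number score per peak, whose scale the authors did not state in the sources used here. The score was used only to describe and rank peaks within a list. Its log2 was used only for shared peaks, in the correlation between pairs and in the score ratio of replicate 2 to replicate 1. PCR duplicates, if kept, would raise scores, and multi-copy genes depend on how the aligner placed reads that match several copies. The lists hold no counts, folds or summits, so depth is unknown and no interval on enrichment was computed. Intervals on shares of peaks cover counting error only.

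Starts were converted to count from 1. Genes were taken from a RefSeq gene table of the assembly GRCh38.p14, the assembly that hg38 names. For each chromosome name the table also lists genes of unlocalized and alternate sequences, and 718 such genes were left out. The 58961 genes kept included 19866 protein-coding genes. The table has no strand, transcripts or sequence, so several points of the plan fixed before the data were examined were changed. A gene end is either annotated end of the gene instead of the transcription start of each transcript, with a window of 1000 bp. Exons and introns were not separated, motifs were not tested, a filter on masked repeats was not applied, and random positions were drawn within the annotated span of each chromosome without removing assembly gaps. Unfilled gaps draw some random positions away from genes, which lowers the random share at gene ends. For 16 genes of the lists that passed, the direction of transcription was taken from general knowledge after the regions were seen.

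Peaks were called shared when they overlapped by at least 1 bp, and each connected set of overlapping peaks of both replicates was 1 region. Overlap and position were tested against 1000 random placements that kept chromosome and width (seeded, one-sided). Peaks on sequences without a span were put out of reach of any other peak, a correction made after a first run in which they stayed in place. Scores were compared with 100000 permutations. Shares carry exact Clopper-Pearson 95% intervals. Gene lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes (for the small nuclear RNA list, all other annotated genes), with Benjamini-Hochberg adjustment over 24 lists at a threshold of 0.05. The 24 lists were written from general knowledge before the data were examined. Chromosomes 1 to 22 and X were tested with exact binomial tests; 2 peaks in each list lay outside them. The chromosome test was restricted to these after a first run.

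The genes named were fixed by a rule before the data were examined. Genes with a region at an end were ordered by the lower of the region's percentiles in the lists, and the first 15 were named. Up to 4 members of each gene list with a region, ARID1B itself, and the first 5 regions over 10000 bp from every gene end were named besides. Where few members of a list had a region they were named, except for single genes that are not reported here. Genes named for clusters, for small nuclear RNAs beyond the first 4, for variant histones and for peaks of 1 replicate were chosen after their values were seen.

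Alternatives fixed beforehand were the peaks of each list that score at or above its median, chromosomes 1 to 22 and X alone, 50% reciprocal overlap, centres within 200 bp, windows of 500 and 5000 bp, random placement at matched distances from gene ends, and each replicate's full list in place of the shared regions. Matched positions were put at each peak's own distance from a gene end drawn at random, without a check that this end was the nearest. Alternatives added after the data were seen moved regions by 50 to 500 kb, placed regions beside random gene ends, counted neighbouring regions once, left out regions at several genes, and left out small nuclear RNA regions that also lay at an end of a protein-coding gene. The overlap and list tests were tested on simulated data: a planted overlap of 60% of 1800 peaks was recovered as 60%, and a planted list was called (Fisher's exact test, adjusted p = 1.08e-05) with 0 of 23 other lists. A planted share of 16.0% at gene ends was read as 19.5%, because randomly placed regions also reached gene ends. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.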

Results

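Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate ARID1B on the genome of HEK293FRT cells, a derivative of the human embryonic kidney line HEK293. ARID1B is a DNA-binding subunit of the BAF (SWI/SNF) chromatin remodelling complexes, which move and evict nucleosomes. The series held 3 samples, of which 2 were ARID1B ChIP replicates and 1 was an input. A peak list was read for each replicate, and the input was not analysed here. The lists held 1792 peaks in replicate 1 and 1820 in replicate 2, covering 576 and 607 kb with median widths of 290 and 300 bp. Sequencing depth is unknown, because the lists carry no read counts. Each peak carried a score given by the authors, from 10 to 1537 in replicate 1 (median 74) and from 11 to 1642 in replicate 2 (median 75). All positions are on the human genome build hg38. The labels do not say whether the replicates came from separate cultures, so the comparisons measure a spread that may be technical.

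The first comparison asked whether both replicates found the same places. The highest-scoring peak of both lists lay inside MAP3K15, a protein kinase gene, at chromosome X:19451957-19452459, with scores of 1537 and 1642. The next by the lower of its ranks in the lists lay at an end of SP2, a gene for a GC-box-binding transcription factor, at 17:47895763-47896498, with scores of 1210 and 1461. Altogether 1317 of 1792 replicate 1 peaks (73.5%, exact Clopper-Pearson 95% interval 71.4 to 75.5) and 1317 of 1820 replicate 2 peaks (72.4%, 70.2 to 74.4) overlapped a peak of the other list by at least 1 bp. Random placement of the replicate 2 peaks gave a mean of 0.905 shared peaks and at most 7 in 1000 placements (one-sided permutation p = 0.001, the smallest possible). The overlapping peaks formed 1313 regions found in both replicates, 1312 of them on chromosomes with gene annotation.

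Sharing rose with the score. Of the 448 lowest-scoring peaks of replicate 1 48.4% were shared and of the 448 highest-scoring 98.2%. Of the 455 lowest-scoring peaks of replicate 2 47.5% were shared and of the 455 highest-scoring 98.0%. The 100 highest-scoring peaks of each list were all shared, which leaves a lower 95% bound of 96.4%. Among 1305 peaks that paired one to one, the log2 scores correlated with a Spearman rho of 0.712 and a Pearson r of 0.740 (permutation p = 1e-05 for each, the smallest possible). These correlations run across peaks, which are not independent replicates.

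**Figure D1:**
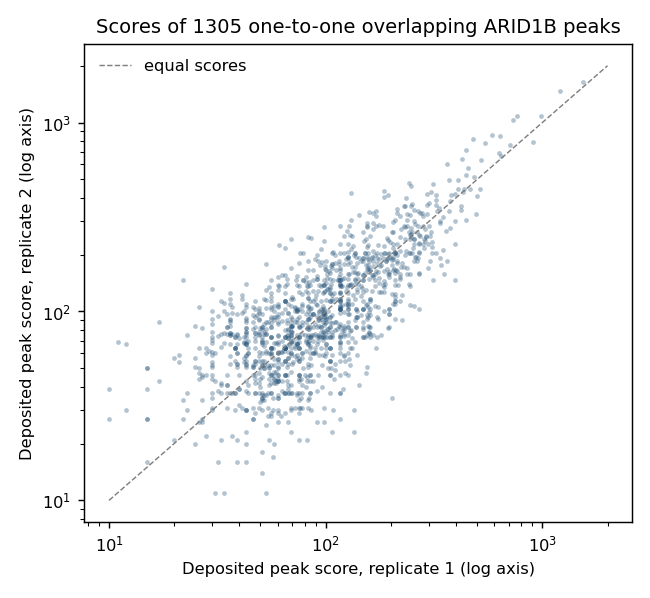
Authors' peak scores of the 1305 one-to-one overlapping ARID1B peaks, replicate 1 on the x axis and replicate 2 on the y axis, both on log axes without a unit. Each point is 1 pair of peaks and the dashed line marks equal scores; the pairs follow the line with a Spearman rho of 0.712, and the MAP3K15 peak lies at the upper right.

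The next comparison asked where in relation to genes the shared regions lay. Among regions within 1000 bp of an end of a protein-coding gene, that of SP2 was followed by those of DNM2, the gene of the membrane-scission GTPase dynamin 2 (19:10717526-10718157; scores 990 and 1089), WDR27 (6:169425102-169425960; 732 and 1038) and SP1, a relative of SP2 (12:53379473-53380188; 635 and 848). Regions with scores of 425 to 632 in replicate 1 followed at EVI5L, at NLK, which encodes a kinase of Wnt signalling, at CIC, which encodes a repressor, at DRC3 and TOM1L2, which shared a region, and at RFX1, a transcription factor gene. The region at 9:128067300-128067710 reached NAIF1 and SLC25A25, and that at 19:6424807-6425638 reached KHSRP and SLC25A41. The last of the first 15 genes was CDK2, a cell-cycle kinase gene, with scores of 364 and 601 at 12:55973652-55974153; that region also reached RAB5B.

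In all, 164 of 1312 regions (12.5%, 95% interval 10.8 to 14.4) lay at a gene end, against 3.16% ± 0.494 (SD of 1000 placements) for random positions, a 3.95-fold excess (one-sided permutation p = 0.001, the smallest possible). The excess was 1.66-fold within 5000 bp. They reached 209 genes, and 42 of the 164 regions reached more than 1 gene. Gene bodies away from the ends held 43.9% of regions against 41.8% at random (p = 0.0639), and 43.6% lay outside protein-coding genes against 55.1% at random (one-sided permutation p = 0.001 for a lower share, the smallest possible). The median distance to the nearest gene end was 49.4 kb, within the 95% range of 48.8 to 63.6 kb of the random medians. With all replicate 1 peaks the share at gene ends was 10.3%, and with all replicate 2 peaks 15.6%. The direction of transcription was not used in these counts, so a gene end is a transcription start or a transcription end.

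Most of the regions were distal. Of 1312 regions, 988 (75.3%) lay more than 10 kb from every end of a protein-coding gene. A random share at this distance is not given here. Within 5000 bp of an end lay 19.1% of regions against 11.5% at random, so no preference for distal positions is shown. The first by score was the MAP3K15 region, 63.0 kb inside that gene. It was followed by a region at 14:36834938-36835670 (scores 902 and 785) inside SLC25A21, a mitochondrial carrier gene; the nearest gene end, 156 kb away, was that of PAX9, a developmental transcription factor gene. A region 216 kb from ZNF703, which encodes a zinc-finger corepressor, lay inside the long non-coding RNA gene LINC01605 at 8:37479255-37479896 (707 and 763). The next lay in VPS13D, a gene for a lipid transfer protein, at 1:12478048-12478696 (586 and 863), 33.4 kb from its nearer end. The last of these 5 lay outside annotated genes at 8:37302391-37303220 (642 and 667), 366 kb from KCNU1, a potassium channel gene. No shared region lay inside ARID1B itself (6:156776026-157210779). It was the nearest gene to 1 region, at 6:156557331-156557688, with scores of 57 and 17, 218 kb away.

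Several distal stretches held many regions. ZNF608, a zinc-finger gene on chromosome 5, was the nearest protein-coding gene to 20 regions spread over 1222 kb, where random placement gave a mean of 0.918 and at most 4. ZNF703 was nearest to 10 regions (random mean 0.144), GMDS, an enzyme gene of fucose metabolism, to 9 (0.509), and AUTS2, a neurodevelopmental gene, to 8 (1.05). NKAIN2 and NR2F2, the latter a nuclear receptor gene, were each nearest to 7, and FRMPD4, RAD51B and SOX9 each to 6. When regions separated by at most 100 kb were joined, 7 clusters of 5 or more regions appeared, holding 45 regions, against a mean of 0.011 and at most 1 in random placements (one-sided permutation p = 0.001, the smallest possible). The clusters lay at ZNF608 (10 regions at 5:124629144-124747504 and 6 more at 5:125176037-125485623), at ZNF703 and KCNU1 (8 regions), at RAD51B (6 regions), and at PAX9, GMDS, and GRAPL with GRAP (5 regions each). The GRAPL and GRAP cluster (17:19061942-19190178) included the region of SNORD3A, an RNA gene with several copies that also counts in a gene list below. The counts of nearest regions and of clusters were chosen after the positions were seen.

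**Figure D2:**
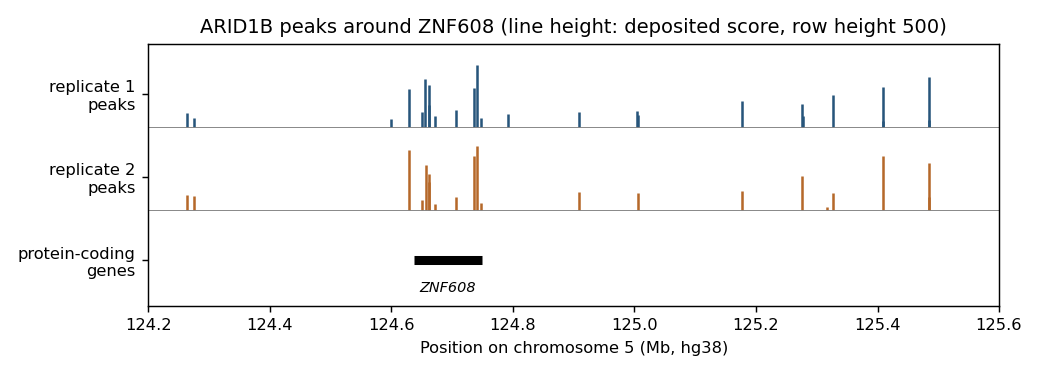
ARID1B peaks around ZNF608 on chromosome 5, with the position in Mb (hg38) on the x axis. Vertical lines are the 25 peaks of replicate 1 (upper track) and the 21 peaks of replicate 2 (middle track), their height proportional to the authors' score on 1 scale for both, and the black bar is ZNF608; peaks of both replicates stand in and beside the gene and again to its right.

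The next comparison asked which of 24 gene lists, fixed before the data were examined, had members with a shared region within 1000 bp of either end. Genes of small nuclear RNAs, the RNA parts of the splicing and RNA-processing machinery, stood first: 13 of 31 genes of the list of small nuclear and 7S RNAs (41.9%, 95% interval 24.5 to 60.9) had a region, against 0.616% of all other annotated genes. The odds ratio was 117 (Fisher's exact test, two-sided, adjusted p = 1.05e-19 over the 24 lists). The highest scores in the list were at RNU7-1, the gene of the RNA that processes histone messages (12:6943779-6944264; 177 and 286), at SNORD118, the U8 gene (17:8172965-8173628; 171 and 163), and at RNU11, a minor spliceosome gene (1:28648555-28649141; 105 and 160). RNU1-1, a U1 gene of the major spliceosome, followed with scores of 95 and 136, and then SNORD3A, a U3 gene, with 87 and 166. Of the 13 regions 6 also lay at an end of a protein-coding gene, among them those of RNU7-1 (C12orf57), SNORD118 (TMEM107) and RNU11 (TAF12). Without these, 7 of 31 genes had a region (22.6%, exact adjusted p = 3.94e-12).

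The list was then divided by the RNA polymerase known to transcribe each gene, a division made after the regions were seen. Of 20 genes read by RNA polymerase II, 13 (65%, 40.8 to 84.6) had a region. Of 11 genes read by RNA polymerase III, among them RN7SK, RMRP, RPPH1 and the U6 genes, 0 had one, with an upper 95% bound of 28.5% (Fisher's exact test, two-sided, p = 4.38e-04). Without regions at protein-coding genes it was 7 of 20 against 0 of 11 (exact p = 0.0331). Over the whole annotation, genes of the class snRNA had a region in 12.1% of cases (18 of 149), protein-coding genes in 1.05% and long non-coding RNA genes in 0.622%. None of 429 transfer RNA genes had one, with an upper 95% bound of 0.856% (Fisher's exact test against protein-coding genes, adjusted p = 0.0450). At so short a gene the windows of both ends largely coincide, which leaves less sequence to reach than at a long gene. Gene length was not corrected for, so this test cannot show that transfer RNA genes are avoided.

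HOX genes, which pattern the body axis, had a region at 5 of 39 members (12.8%, 4.30 to 27.4; odds ratio 14.1; Fisher's exact test, adjusted p = 4.23e-04), in 4 separate regions. All lay among the neighbouring HOXA genes of chromosome 7 and HOXB genes of chromosome 17. Fisher's exact test counts neighbouring genes as independent, so its p may be too small. HOXA9 had the highest scores (7:27165505-27166266; 205 and 264), followed by HOXA4 (127 and 83) and HOXB4 (117 and 83), and HOXB3 and HOXB5 shared 1 region (37 and 106). By the known direction of these genes, 4 of the 5 were reached at the transcription start and HOXB5 at the transcription end.

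Ribosomal protein genes had a region at 8 of 81 members (9.88%, 4.36 to 18.5; odds ratio 10.7; Fisher's exact test, adjusted p = 2.62e-05). RPL41 (125 and 266) and RPL4 (53 and 178) led, RPL17 and RPL13 followed, and RPL18, RPL26, RPS2 and RPS28 made up the rest. All 8 were reached at the transcription end by the known direction of the genes, a reading added after the regions were seen, and 6 of the 8 regions also reached another protein-coding gene. The call ended among peaks scoring at or above the median of their list (1 of 81, exact adjusted p = 0.769) and without regions at several genes (2 of 81, adjusted p = 0.355); the adjusted p went down to 1.64e-10 with all replicate 2 peaks.

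Housekeeping genes had a region at 3 of 36 members (8.33%, 1.75 to 22.5; Fisher's exact test, adjusted p = 0.0381). EIF4A1, a translation factor gene (100 and 186), and GAPDH, a glycolysis gene (69 and 84), were reached at the transcription end. This call ended in the same settings (exact adjusted p = 0.0965 and 0.434), and the adjusted p went down to 2.43e-05 with all replicate 2 peaks.

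No other list passed. Of subunits of the BAF and PBAF complexes, 1 of 29 had a region (SMARCD2, 81 and 153; exact adjusted p = 0.488), and of other chromatin regulators 2 of 62 (BRD2 and KAT6B; adjusted p = 0.416, but 0.0204 with all replicate 2 peaks, where 5 members had one). Immediate early genes had 2 of 32, FOS (41 and 122) and JUN (54 and 37), and Notch and TGF-beta signalling 2 of 34, HES1 (140 and 127) and SMAD6 (63 and 156), each at an adjusted p of 0.170. Oxidative phosphorylation genes had 2 of 83 (ATP5F1B and NDUFB10). Single members were reached in the lists of cholesterol synthesis (HMGCS1), kidney development (FOXC1), neural development (HES1), E2F and cell cycle (CDK2) and blood cell markers (CD68), with adjusted p from 0.488 to 0.635. Zinc-finger symbols had 3 of 509 (ZNF687, ZNF143 and ZNF503; exact adjusted p = 0.613). Replication-dependent histone genes had 0 of 69 and olfactory receptor genes 0 of 387, with upper 95% bounds of 5.21% and 0.949%. The variant histone genes H2AZ1 (43 and 53) and H2AZ2 (30 and 91), outside the histone list, each had a region. The olfactory list passed, as fewer, with all replicate 2 peaks (exact adjusted p = 0.00729) and within 5000 bp (0.0137). The lists of Hippo, Wnt and p53 targets, heat shock and unfolded protein genes, neuronal genes, hepatocyte markers and keratin-associated genes had 0 members with a region.

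**Figure D3:**
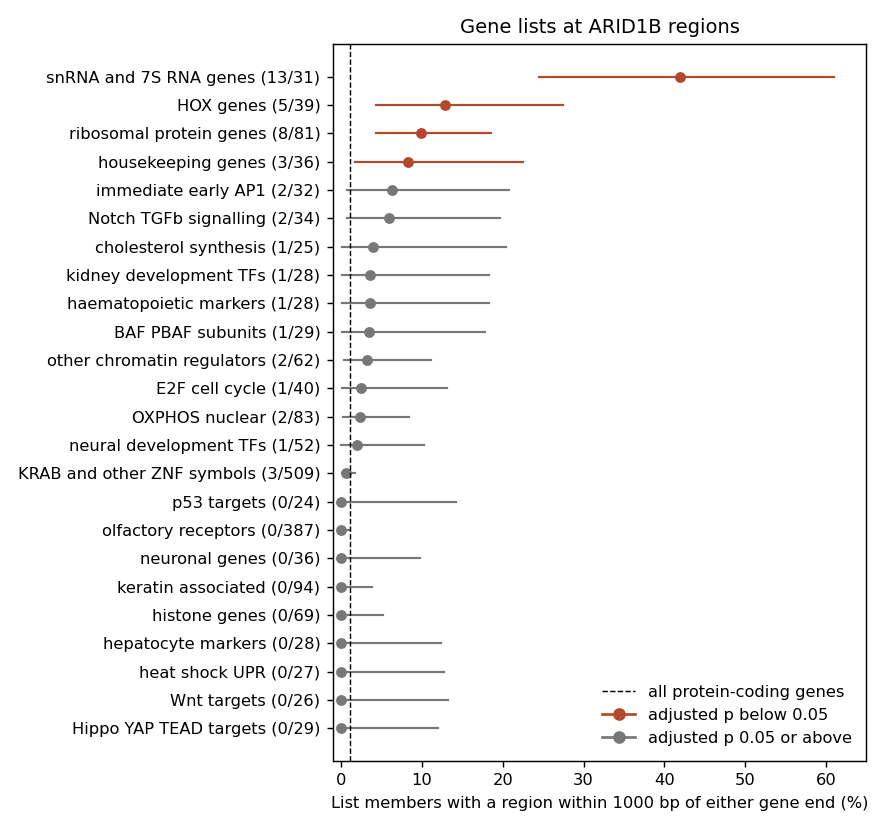
Percent of the members of each of the 24 gene lists with a shared ARID1B region within 1000 bp of either gene end (x axis), with the number of members in brackets. Points are percents, lines are exact 95% intervals and the dashed line marks all protein-coding genes; the small nuclear RNA list stands apart at 41.9%, and HOX, ribosomal protein and housekeeping genes follow at 12.8%, 9.88% and 8.33%.

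The last comparison of the shared regions asked whether they spread over the chromosomes as the genes do. Relative to its protein-coding genes, chromosome 5, which holds the ZNF608 clusters, had 117 regions where 59.1 were due (1.98-fold, exact binomial test, adjusted p = 2.09e-10 over the chromosomes). Chromosome 18 had 1.97-fold, chromosome 14, with PAX9 and RAD51B, 1.70-fold, chromosome 10 1.59-fold, chromosome 6 1.54-fold and chromosome 3 1.29-fold the regions due. Chromosome 11 had 33 where 85.8 were due (0.385-fold, exact adjusted p = 4.93e-10), and chromosomes 12, 16, 19, 22 and X also had fewer. Chromosomes 3 and 12 no longer deviated among peaks scoring at or above the median of their list, nor did chromosome 12 with neighbouring regions counted once. In all, 12 chromosomes deviated (exact binomial test, two-sided, adjusted p under 0.05). Relative to annotated length, 12 deviated as well, but 8 among peaks scoring at or above the median of their list and 8 with neighbouring regions counted once. Chromosome 19, the richest in genes, then had 1.85-fold the regions due (exact adjusted p = 3.45e-04) where it had 0.515-fold relative to genes. By length, chromosomes 18 and 3 had 0.985-fold and 1.04-fold and did not deviate, so their excess held only relative to genes. Chromosome 5 had 1.46-fold by length (exact adjusted p = 3.09e-04), but no longer deviated by length with neighbouring regions counted once.

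Peaks found in 1 replicate only differed between the replicates in where they lay. Of 475 peaks of replicate 1 alone, 19 (4.0%, 2.43 to 6.18) lay at a gene end, and of 503 peaks of replicate 2 alone, 120 (23.9%, 20.2 to 27.8). The odds ratio was 7.52 (95% interval 4.50 to 13.2; Fisher's exact test, two-sided, p = 2.00e-20). The peaks of replicate 2 alone reached 7 further ribosomal protein genes, among them RPS19 and RPL10 (7 of 81, Fisher's exact test, adjusted p = 9.36e-05), 4 HOX genes (HOXA5, HOXA9, HOXB4 and HOXB8; adjusted p = 0.00209) and 5 housekeeping genes (ACTB, EIF4A1, TUBA1B, VCP and VIM; adjusted p = 1.14e-04). ARID1A, the gene of the alternative to ARID1B in the complex, and ACTB were the BAF members reached (2 of 29, exact adjusted p = 0.108). No list passed for replicate 1 alone, where the lowest adjusted p was 0.265. On chromosome 19 there were 3 peaks of replicate 1 alone and 25 of replicate 2 alone (Fisher's exact test, adjusted p = 6.22e-04), on chromosome 17 13 and 43, and on chromosome 13 27 and 6 (adjusted p = 9.37e-04 for both). Chromosome 10 held 41 and 20 (exact adjusted p = 0.02). The scores of both sets were low, with medians of 49 and 50 and highest values of 138 and 176. These peaks were compared after the lists had been seen.

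**Figure D4:**
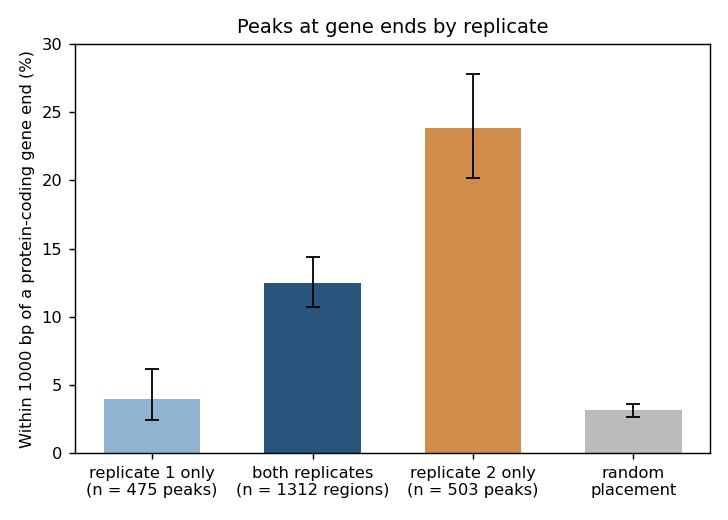
Percent of ARID1B peaks within 1000 bp of an end of a protein-coding gene (y axis, from 0) for peaks of replicate 1 alone, regions of both replicates, peaks of replicate 2 alone and random placement. Error bars are exact 95% intervals, and for random placement the SD of 1000 placements; the bars stand at 4.0%, 12.5%, 23.9% and 3.16%.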

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

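The peak below was singled out after the lists were seen. A signal appeared outside the chromosomes used for the tests of position: each list held 1 peak on the same unlocalized sequence of chromosome 1, at 21634-21936 in replicate 1 and at 21613-21962 in replicate 2. The score was 82 in each list, close to the medians of 74 and 75. These peaks entered the count of shared peaks and the correlation of scores, but no comparison with genes.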

How the results depend on the processing

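Alternatives that moved regions by 50 to 500 kb, placed regions beside random gene ends, counted neighbouring regions once, left out regions at several genes or left out small nuclear RNA regions at a protein-coding gene were added after the data were seen. The number of gene lists past the threshold with a higher share of members reached than of other genes fell from 4 to 2 among peaks scoring at or above the median of their list and to 2 without regions at several genes; HOX and small nuclear RNA genes passed in both. The cause was not tested. Across the replicates' full lists it was 4 to 5 (the olfactory list, which passed as fewer with all replicate 2 peaks, is not counted), the share at gene ends 10.3 to 15.6%, and the number of chromosomes that deviated from gene counts 12 to 14. For the single gene lists, 162 of 169 values under the alternatives kept their side of the threshold, 4 fell below it and 3 came past it. Direction was checked only for lists that passed in the main test, and 0 of these turned round. Other lists could change direction uncounted. Immediate early genes, for example, went from 2 of 32 to 0 of 32 among peaks scoring at or above the median. Hippo targets went from 0 to 1 of 29 with all replicate 1 peaks. The shared percent of replicate 1 stayed between 71.1 and 73.5, the Spearman rho between 0.651 and 0.714. The share at gene ends was 10.2% within 500 bp, against 1.90% at random (5.37-fold), and 19.1% within 5000 bp, against 11.5% at random (1.66-fold). The number of chromosomes that deviated from annotated length fell from 12 to 8 both among peaks scoring at or above the median and with neighbouring regions counted once; chromosomes 9 and 10 were lost in both. Against gene counts it was 11 in each of these settings, without chromosome 12 in both. The motif alternatives, the filter on masked repeats, the transcription start alone and another peak value were not run, and a threshold below the authors' own cannot be set from these lists. Depth, unknown here, limits what a peak missing from 1 list means.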

Other observations

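All tests in this part were chosen after the result was seen, except the flank densities and the count of facing ends, which were set before their values were computed. Distal regions lay beside several genes of developmental transcription factors. Of 988 regions over 10 kb from every gene end, 6 had SOX9 as nearest gene, 2 each MEIS1, OTX2 and TCF4, and 1 each LHX2, MEIS2, OLIG3 and SOX2. The neural development list as a whole had 17, against 7.79 at random positions (permutation test, adjusted p = 0.149 over the lists). Against matched positions, put at each region's distance from a randomly drawn gene end, the adjusted p was 0.023. That end need not be the nearest, and the draws favour gene-dense sequence. Keratin-associated genes had a mean of 3.75 at matched and 0.07 at random positions. The matched p therefore cannot decide whether distal regions prefer the neural list. From the kidney development list, GATA3 was nearest to 2 and FOXC1 and SIX2 to 1 each. That list had 4, against 4.67 at random and 1.56 at matched positions (permutation test, adjusted p = 0.454 against the latter). The zinc-finger list had 32 against 19.4 at random, with the same adjusted p of 0.149 (0.781 against matched positions), and 17 of its regions were nearest to ZNF608 and 10 to ZNF703. Other lists gave RNF43 3, PTPN14 3, MAP2 3 and UQCRFS1 4 regions, and none of these lists passed.

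The neural and kidney development lists together had 21, against 12.5 at random positions and 3.94 at matched positions. Because these lists were pooled after their counts were seen, this count cannot decide whether distal regions may prefer developmental transcription factor genes, and SOX9 alone gave 6 of the 21.

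A hypothesis was that regions at gene ends may lie at the transcription start more often than at the other end. Genes named as having a divergent partner, whose start is the end that faces the partner, gave a test without strand. Among 563 such genes, 9 regions reached the facing end (among them those at SP2, KPNB1, EIF2AK3 and NFE2L1) and 2 the other end (LRRC8C and IDH3B), which is 81.8% (one-sided exact binomial p = 0.0327). The facing end of TAF12 was reached by the region that also lay at RNU11, and the test was not repeated without it. With 9 regions against 2, the result may rest on that region, so a preference for the transcription start is not settled. At ribosomal protein genes 8 of 8 regions reached the transcription end of those genes. Of these, 6 also reached another protein-coding gene, and only the regions at RPL13 and RPS28 did not. Which end of the other genes was reached was not determined, so this set cannot decide the question.

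Peaks of replicate 2 alone lay at gene ends more often than those of replicate 1 alone, 23.9% against 4.0%. Weak peaks near the authors' threshold, without a difference between the libraries, would leave the scores of shared peaks even. Instead the median log2 score ratio of replicate 2 to replicate 1 was 0.61 at 160 shared peaks at gene ends and -0.02 at 1145 others, a difference of 0.63 (two-sided permutation p = 2e-05), which argues against it. A difference that follows gene-dense sequence remains open: away from gene ends, the median number of gene ends within 500 kb was 12 around peaks of replicate 2 alone and 9 around those of replicate 1 alone, a difference of 3 (permutation p = 2e-05), and what in the libraries may differ in this way was not tested. The design has 1 group, so no biological explanation was tested.

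Small nuclear RNA genes carried regions at 13 of 20 genes read by RNA polymerase II. If any strongly transcribed short gene were enriched, the replication-dependent histone genes would carry regions as often. Of these 0 of 69 did, with an upper 95% bound of 5.21%. The lower bound for the small nuclear RNA genes was 40.8%, or 15.4% without regions at protein-coding genes. The histone genes thus did not share the enrichment, but this class was compared after its count was seen. Ribosomal protein genes (8 of 81) and housekeeping genes (3 of 36) had regions more often than other genes. Those calls ended among peaks scoring at or above the median of their list. The broader explanation therefore stays open. If reads of near-identical copies gathered at 1 locus, genes with a single locus would carry none beyond the 1.05% of protein-coding genes, but RNU7-1, RNU11, RNU12 and SNORD118 did and RNU4ATAC did not, 4 of 5 with a lower 95% bound of 28.4%; this class was narrowed after a first run. All 4 of these regions also lay at an end of a protein-coding gene, and without such regions it was 0 of 5 single-locus genes and 7 of 15 genes with several copies, so gathered copies stay open. Open chromatin caught without the antibody stays open too, since the input was not analysed here, and no biological explanation was tested.

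The stretches spanned by all regions nearest to ZNF608 (20 regions) and to ZNF703 (10 regions) held 16.4 and 28.9 regions per Mb, against 0.435 over the genome. A gain of a chromosome segment that reaches 2 Mb or more to each side would raise the flanks too. The flanks from 1 to 3 Mb held 2 regions beside ZNF608 (0.5 per Mb) and 0 beside ZNF703. The upper 95% Poisson bounds were 1.81 and 0.922 per Mb, far below the stretches themselves. The flanks thus did not share the density of the stretches. But the stretches were chosen for their density and bounded by their own regions, so lower flanks were in part built in. The values therefore cannot decide whether a gain added to the density. Both bounds lie above 0.435, so a gain that raised the flanks less than the stretches cannot be told from none. A gain limited to these stretches stays open without the input, and no biological explanation was tested.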
